A study of Mus musculus with 6 samples.

How the data were processed

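Gene expression was measured in whole hearts of 6 mice with 1 Affymetrix 3' expression array per heart. The labels describe 3 wild-type hearts and 3 hearts of Pgc1b knockout mice as biological replicates, on a mixed sv129 and C57BL/6 background. The targeted gene, named Ppargc1b in current tables, encodes a transcriptional coactivator of nuclear receptors. Per the labels' protocols, hearts were snap frozen, total RNA was extracted with Trizol followed by a column kit, and a small amount was amplified with a whole-transcriptome kit before conversion to labelled cRNA. Each array therefore reports RNA after 2 rounds of amplification, and differences in amplification between samples are part of the spread between arrays.

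The deposited values are on the log2 scale, with 1 column per array, and were made by the authors with GCOS, Partek and RMA, per the submitters' processing notes, which as used here give no version, role or order for them. RMA corrects the background, sets all arrays to 1 common distribution and summarises the probes of a probe set, so a shift shared by all genes of an array is removed before deposit and changes are relative to the other genes. The log2 scale was checked on the values, which lie between 2.56 and 14.1. The genome build is not given in the sources used here, and no coordinates are reported.

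Values were present in 707 of the 45101 rows of the table, or 1.57%. These were 643 probe sets for genes and 64 control probe sets for spiked RNAs and reference transcripts. The other 44394 rows were blank in the table used here and were not analysed here. Ppargc1b was among the genes not analysed here, so the genotype labels were not checked against the targeted transcript, and all counts refer to the measured genes only. Every column was mapped to a sample by the labels, and 0 columns stayed unmapped. A platform annotation, which can be old, named 1 gene symbol for 597 of the 643 probe sets, several symbols for 26 and none for 20. All 597 matched a mouse RefSeq gene table of assembly GRCm38.p6 by gene ID, and current symbols were taken from it. Probe sets with several symbols or none were left unnamed and out of the gene-level tests. The 597 probe sets covered 494 genes, and each of the 88 genes with more than 1 probe set was represented by the one with the highest mean over all 6 arrays. In 29 of those 88 genes, probe sets of the gene differed in the sign of the difference.

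Knockout and wild-type hearts were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, constant prior variance, two-sided) on the log2 values without further normalization, without a filter on dim probe sets and without a covariate. The p-values were adjusted by the Benjamini-Hochberg method over the 494 genes, and a gene was called at an adjusted p under 0.05. The number at an unadjusted p under 0.01 was counted as well. Differences are given as knockout minus wild-type on the log2 scale with 95% confidence intervals, and group levels as mean ± SD of 3 arrays. The intervals come from limma for single genes and from an ordinary linear model of the array means for groups of genes. Depth does not apply to arrays, and their number limits the precision. For values computed once per array, an exact two-sided permutation test was used, which with 3 arrays against 3 cannot give a p below 0.1.

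The 45 gene lists, made of pathways, complexes and markers of 16 other cell types or tissues that a heart sample could hold, were fixed with the tests, the alternatives and the rule for named genes before the data were examined. At least 1 gene was measured in 24 of the lists, and 21 lists, 13 of them marker lists, had no measured gene. Lists with at least 5 measured genes, of which there were 5, were tested with limma's camera with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over these lists. Camera asks whether the genes of a list moved more than the other genes. With the preset correlation its p-value treats genes, not hearts, as the replicates. Single members were also adjusted over the list alone. Named genes were to be up to 12 per direction with the largest change among called genes without overlap of the groups, filled with genes of an unadjusted p under 0.01 without overlap, then the 2 members of each list with the smallest p, and a fixed set of cardiac and metabolic genes. Slc25a3, Atp5g2, Cox6c, Mrpl20, Mrpl27, Mrpl28, Mmp2, Scd2, Elovl5 and Sqle are outside this rule. They were named after their values were seen to describe their lists, and are not among the genes followed through the alternatives. Other genes outside the rule are named only where stated.

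The control probe sets stayed out of the tests. The mean over 18 hybridisation spike probe sets (BioB, BioC, BioD and Cre) and the mean over 24 poly-A spike probe sets (Dap, Lys, Phe and Thr) of each array were used as measures of array handling and of labelling. Further groups were added after the values had been seen, namely the union of the 9 mitochondrial lists as 1 list, and the cytosolic ribosomal protein genes.

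The alternatives were a replicate block, further or no normalization steps, other rules for genes with several probe sets, filters on dim genes, other variance models, other thresholds, an estimated inter-gene correlation, the tests fry and camera on ranks, removal of genes on the chromosome of Ppargc1b, and leaving out each array in turn. Covariates for the spike levels and for the Actb 3' minus 5' difference were added later. The scripts were tested on 20 simulated data sets of 494 genes for this comparison, each with 60 changed genes. Changes of 0.3 on the log2 scale were called in 33.3% of genes, changes of 0.6 in 86.8% and changes of 1.2 in 98.8%, and 3.85% of all calls were false. All 3 sizes were in the same sets, and the larger changes ease the adjusted threshold for those of 0.3. The rate for 0.3 is therefore too high for data with few or no large changes. The ATP synthase list, lowered by 0.15, was called in 17 of 20 simulations, and 1 of 100 unshifted lists was called. Genes were simulated as independent of each other, so these rates do not cover lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.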

Results

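The data describe 494 genes measured in the hearts of 3 wild-type mice and 3 mice lacking Pgc1b, a coactivator that works with nuclear receptors such as the oestrogen-related receptors on genes of mitochondrial metabolism. The title of the study places the comparison among the links between mitochondria and insulin signalling. The 6 arrays had medians between 7.45 and 7.61 on the log2 scale over 643 probe sets. Across genes, arrays of the same genotype correlated at 0.994 to 0.996 and arrays of different genotype at 0.993 to 0.996, where genes are not independent replicates. The first principal component, with 32.6% of the variance between arrays, did not separate the genotypes. It set knockout replicates 2 and 3, at 3.17 and 2.22, apart from knockout replicate 1, at -1.34, and the wild-type arrays, at -0.67 to -1.70.

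Transcripts for the mitochondrial ATP synthase were lower in the knockout hearts as a group. Of the 7 measured genes of the list of ATP synthase subunits and mitochondrial carriers, 6 were lower and 1 was higher, with a mean log2 difference of -0.14. Atp5o, a subunit of the stalk that joins the catalytic head to the membrane part, stood at 12.95 ± 0.05 in wild-type hearts and 12.67 ± 0.02 in knockout hearts (SD, n = 3 each), a knockout level of 82.3% of wild type. Atp5j2, a subunit of the membrane part, stood at 86.2% of wild type (-0.21, 95% interval -0.37 to -0.06). Slc25a3, which carries the phosphate used for ATP synthesis into mitochondria, differed by -0.17, whereas Atp5g2, a subunit of the rotating ring, differed by 0.00. The list shifted downward by camera (adjusted p = 0.00115 over 5 lists), and the call was lost with an adjusted p = 0.0940 with an estimated correlation, the highest of its alternatives, which started at 0.000337. The hybridisation spikes, a control of array handling, were also lower on all knockout arrays (-0.38), and with their level as a covariate the list had an adjusted p = 0.0443 by camera. The Actb 3' minus 5' difference, a measure of RNA quality, was lower as well (-0.13). This is a smaller 3' excess in knockout hearts, which does not point to more degraded RNA there. The same difference of Gapdh was 0.08 in both genotypes. Adjusted over the list alone, 2 of the 7 genes, Atp5o and Atp5j2, fell by limma, and over all genes tested 0 of 7 passed.

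Other parts of the respiratory chain had few measured genes, and their lists were too short for a list test. All 3 measured subunits of complex I, the NADH dehydrogenase, had lower means in knockout hearts, Ndufc1 by the widest margin (-0.18, interval -0.33 to -0.03), and 0 passed adjusted over the list alone. The 3 measured subunits of complex IV, cytochrome c oxidase, also had lower means, with differences of -0.32 for Cox8a, -0.14 for Cox5a and -0.10 for Cox6c, and 0 passed over the list alone. Genes of complexes II and III were not analysed here. In the list of the citric acid cycle and pyruvate dehydrogenase both measured genes fell when adjusted over the list alone. Pdhb, the beta subunit of the enzyme that turns pyruvate into acetyl-CoA, went from 12.28 ± 0.04 to 12.01 ± 0.05 (SD, n = 3), and Suclg1, a subunit of succinyl-CoA ligase, differed by -0.24. Phb2, a scaffold protein of the inner mitochondrial membrane and the 1 measured gene of the quality control list, differed by -0.28 (interval -0.45 to -0.10). None of these single genes passed over all genes tested.

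The mitochondrial ribosome, which translates the proteins encoded by mitochondrial DNA, was mixed. Mrpl43, Mrpl28 and Mrpl27 had differences of -0.29, -0.19 and -0.09, Mrpl20 of 0.01 and Mrpl52 of 0.26. Mrpl43 fell when adjusted over the list alone, the other 4 of the 5 did not pass, and the list did not pass camera (adjusted p = 0.155). Taken as 1 group, a step added after the values had been seen, the 22 measured genes of the mitochondrial lists had a mean level of 11.52 ± 0.01 in wild-type and 11.38 ± 0.02 in knockout hearts (SD, n = 3). The difference was -0.14 (95% interval -0.18 to -0.09), 19 of the 22 genes were lower, and every knockout array lay below every wild-type array. Camera gave p = 1.93e-08 for this union and p = 0.00531 with an estimated correlation, which was 0.015. The exact permutation test of the array means gave 0.1, the smallest p that 3 against 3 allows. Adjusted over these 22 genes, Atp5o, Mrpl43, Pdhb and Phb2 passed. With the hybridisation spike level as a covariate the difference of the union was -0.13 (95% interval -0.22 to -0.05).

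**Figure D1:**
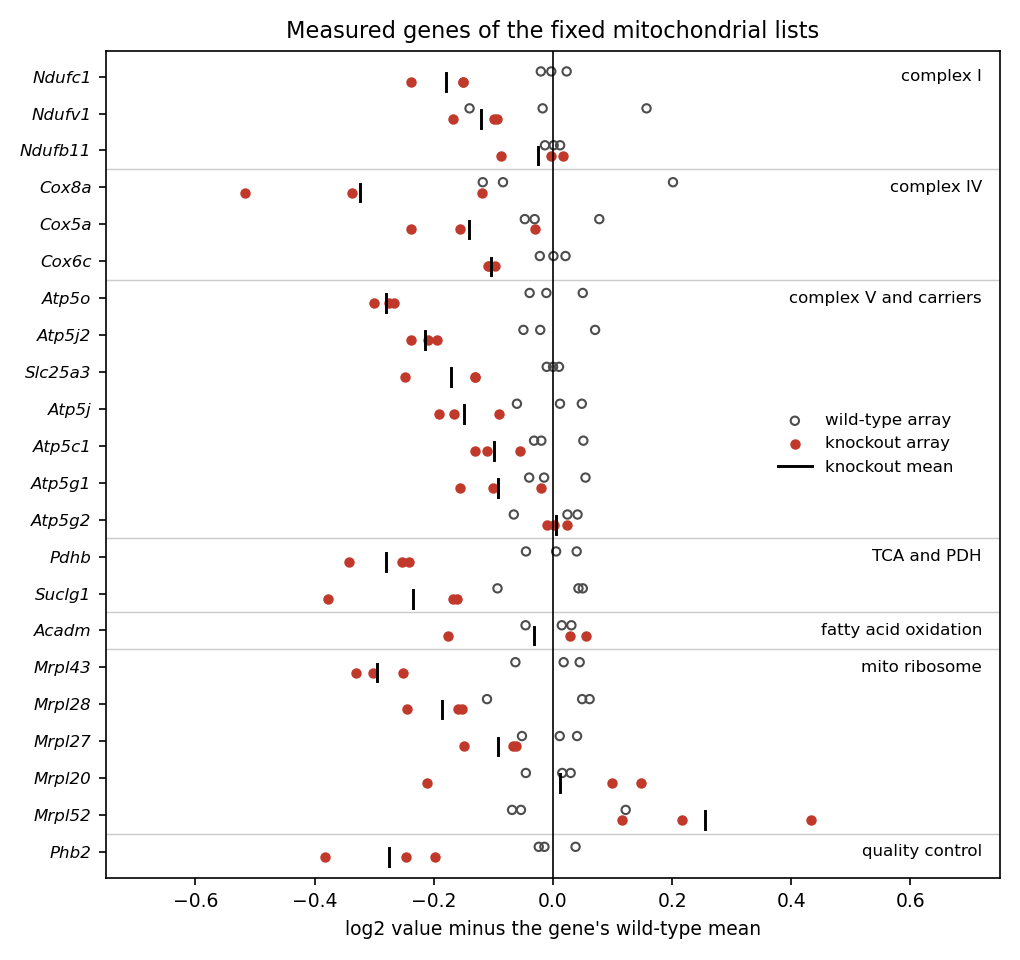
Log2 value of each array minus the wild-type mean of the gene (horizontal axis) for the 22 measured genes of the mitochondrial lists (vertical axis, grouped by list), with open circles for wild-type arrays, filled circles for knockout arrays and a bar at the knockout mean. The knockout mean lies left of 0 in 19 genes and right of 0 in Mrpl52, Mrpl20 and Atp5g2.

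Measured genes of fatty acid oxidation, fatty acid uptake and glucose use did not pass the tests. Acadm, which starts the oxidation of medium-chain fatty acids, differed by -0.03 (interval -0.22 to 0.16), Fabp3, the fatty acid carrier of heart muscle, by 0.04 and Lpl, the lipase that frees fatty acids from circulating lipoproteins, by -0.02. Slc2a4, the insulin-responsive glucose transporter, differed by -0.16 (interval -0.37 to 0.05, and by -0.01 in its dimmer probe set) and the glycolytic enzyme Tpi1 by -0.03. The 5 measured genes for synthesis of unsaturated fatty acids and sterols, targets of SREBP factors, all had lower means, with -0.27 for the desaturase Scd1 (0.03 in its dimmer probe set) and -0.15 for the sterol enzyme Nsdhl. Scd2 differed by -0.22 (0.12 and 0.01 in its dimmer probe sets), while Elovl5 and Sqle differed by only -0.03 each. This list did not pass camera (adjusted p = 0.10, and 0.428 with an estimated correlation), but passed without wild-type replicate 1 (adjusted p = 0.0245) and with the hybridisation spike level as a covariate (adjusted p = 0.00943). Of the insulin signalling list only Pdpk1, a kinase that activates Akt, and the growth factor Igf2 were measured, with differences of -0.04 and -0.02. No gene of these lists passed adjusted over its own list, and the signs of Acadm, Lpl, Tpi1, Pdpk1 and Igf2 changed when single arrays were left out.

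Heart muscle genes outside metabolism were represented by Actc1, the cardiac actin, at 14.11 ± 0.03 in wild-type and 14.12 ± 0.01 in knockout hearts (SD, n = 3), and by the gap junction gene Gja1, with a difference of 0.00 (interval -0.27 to 0.26). After a further quantile normalization the difference of Gja1 was 0.13. The proteasome list, the machinery that degrades tagged proteins, had 5 of 7 genes higher, with 0.24 for Psmc4 (0.03 in its dimmer probe set) and 0.10 for Psmc3, and did not pass (adjusted p = 0.155). The cell cycle list of 5 genes, with Mcm4 at 0.11 and Mcm7 at 0.07, both parts of the replicative helicase, did not pass either (adjusted p = 0.639). Chaperones of the endoplasmic reticulum, Hsp90b1 and Hspa5, differed by 0.15 and 0.11, and by -0.06 and -0.01 without wild-type replicate 3. Antioxidant genes differed by -0.08 for Prdx3, the mitochondrial peroxiredoxin, by 0.05 for Txn1 and by -0.04 for Nnt, the mitochondrial transhydrogenase. The early response genes Ccn1 and Junb differed by 0.12 and -0.04. The signs of Actc1, Gja1, Mcm7, Txn1, Nnt, Ccn1 and Junb also changed when single arrays were left out.

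Tap1, the peptide transporter of antigen presentation and the 1 measured gene of the interferon list, differed by -0.18 (interval -0.36 to -0.01), which did not pass over all genes tested. Matrix genes had lower means, with -0.17 for Fmod, -0.17 for Lox and -0.12 for Mmp2, as had Hif1a, the hypoxia-regulated factor, at -0.11, but without wild-type replicate 3 the difference of Lox was 0.15 and with the hybridisation spike covariate that of Hif1a was 0.00. None of the matrix and hypoxia genes passed adjusted over its list. Of the markers of other cell types, the endothelial receptor Tie1 differed by -0.08, the red cell genes Bpgm and Car1 by 0.31 and 0.13 (Bpgm by -0.05 with the hybridisation spike covariate), and the neutrophil gene Mpo by 0.10, and 0 of these 4 passed. The fibroblast, macrophage, lymphocyte, smooth muscle, fat and skeletal muscle markers were not analysed here, so the cell make-up of the samples is largely open.

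Gene by gene, 12 genes of several functions had an unadjusted p under 0.01 in limma. The 2 higher ones were Npm1, a nucleolar chaperone of ribosome assembly, at 9.31 ± 0.23 in wild-type and 9.74 ± 0.12 in knockout hearts (SD, n = 3), and Il33, a cytokine of the interleukin-1 family, at 6.00 ± 0.14 and 6.33 ± 0.11. The 10 lower ones were led by Sdc1, a heparan sulphate proteoglycan of the cell surface, with a difference of -0.43 (interval -0.69 to -0.16), although its dimmer probe set differed by 0.01, followed by the kinesin Kifc3 with -0.39, the adaptor gene Apba3 with -0.36 and Tmem129, a ubiquitin ligase of the endoplasmic reticulum, with -0.33. The other 6 were Mrpl43, Atp5o, Pdhb and Phb2, all mitochondrial, Cstf2t, a factor of mRNA 3' end processing, with -0.28, and the caspase gene Casp6 with -0.26. In all 12 the 3 knockout values lay outside the range of the 3 wild-type values, but none passed the adjustment in limma, where the smallest adjusted p was 0.301.

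**Figure D2:**
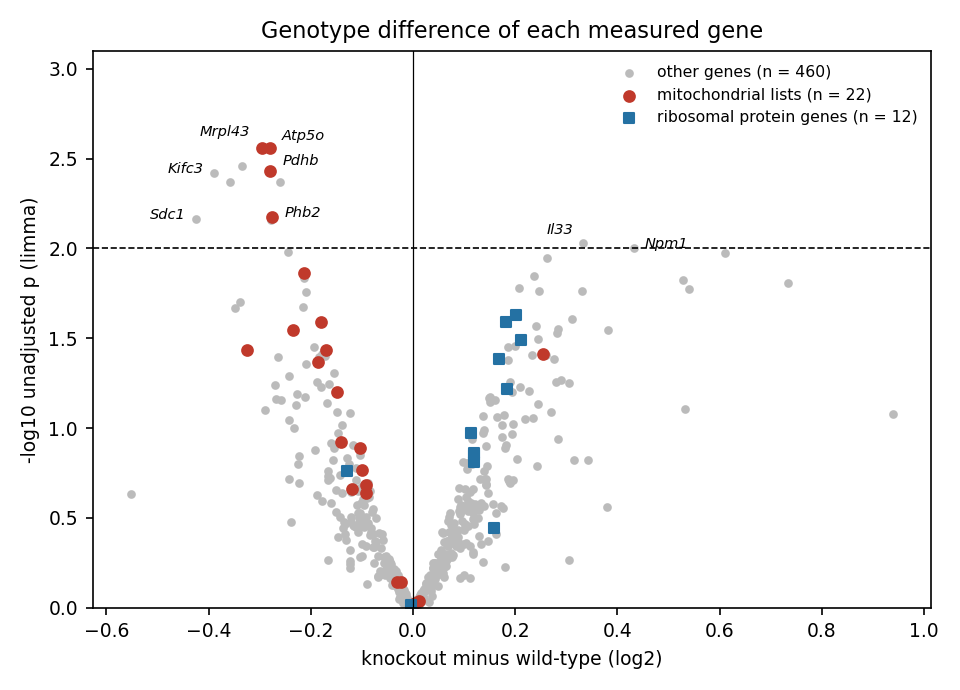
Log2 difference between knockout and wild-type hearts (horizontal axis) against the negative log10 of the unadjusted limma p (vertical axis) for the 494 measured genes, 1 point per gene, with genes of the mitochondrial lists in red and ribosomal protein genes as blue squares, and a dashed line at 2 on the vertical axis. Of the 12 genes with p under 0.01, 10 lie left of 0 and 2 right of 0.

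By count, limma called 0 of the 494 genes at an adjusted p under 0.05, while 57 genes had an unadjusted p under 0.05 (28 higher and 29 lower, with 24.7 given by chance) and 12 an unadjusted p under 0.01 (4.94 by chance). The groups did not overlap in 96 genes, or 19.4%, where chance gives 10%. The count of 12 became 7, 3, 7 and 6 without wild-type replicate 1, wild-type replicate 2, knockout replicate 2 and knockout replicate 3. With a prior variance that follows the expression level limma called 1 gene, Atp5o, which was lower (adjusted p = 0.0369, and up to 0.594 in the other alternatives).

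The control probe sets also differed between the genotypes. The hybridisation spikes, added to each sample in a fixed amount, had a mean of 9.89 ± 0.23 on wild-type and 9.52 ± 0.18 on knockout arrays (SD, n = 3), a difference of -0.38 with every knockout array below every wild-type array (exact permutation p = 0.1, the smallest possible). The margin was narrow, with 9.679 on the highest knockout and 9.688 on the lowest wild-type array. Of the 18 spike probe sets, 7 were lower on all knockout than on all wild-type arrays. The poly-A spikes, which follow the RNA through labelling, differed by 0.06 (exact permutation p = 0.9). The mean over the control probe sets of 18S rRNA differed by -0.35 with overlap of the groups (exact permutation p = 0.3). The excess of the 3' over the 5' probe set of Actb, a measure of RNA integrity and amplification, was 0.75 ± 0.02 in wild-type and 0.63 ± 0.11 in knockout hearts (exact permutation p = 0.1), and that of Gapdh 0.08 in both (exact permutation p = 1).

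**Figure D3:**
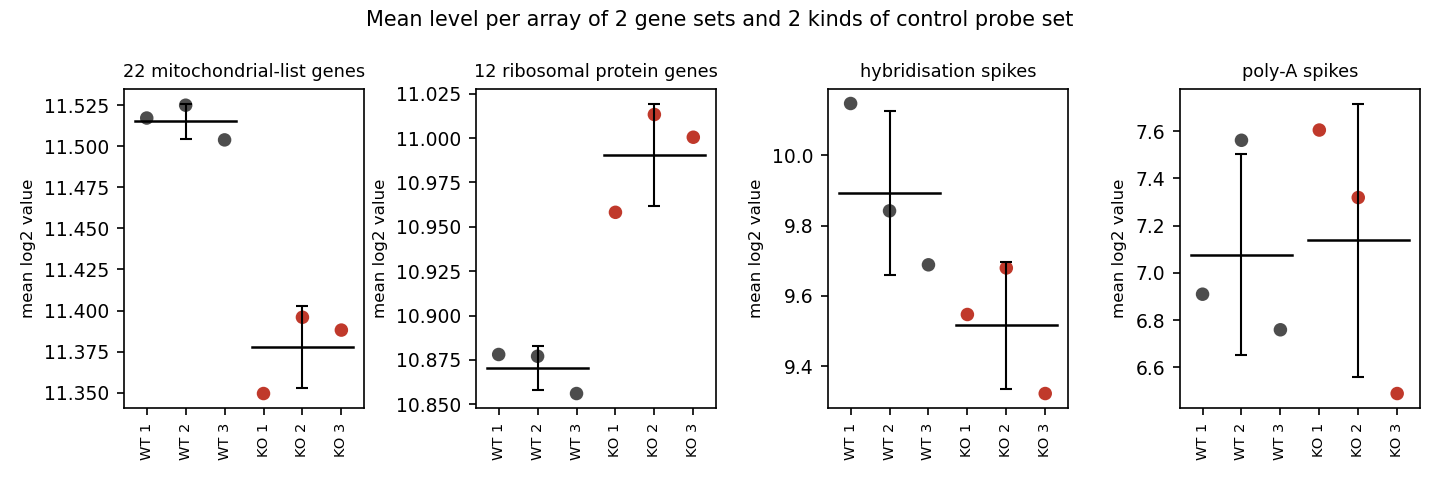
Mean log2 level per array (vertical axes) of the genes or control probe sets named above each panel, with a grey point per wild-type array, a red point per knockout array, and lines for the mean ± SD of each genotype on axes that do not start at 0. The hybridisation spikes and the 22 mitochondrial genes lie lower on all 3 knockout arrays than on all 3 wild-type arrays.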

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

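The tests by which these probe sets were picked were set after the values had been seen. The gene-level comparison left out probe sets that were not the representative of their gene or had several gene symbols or none. In 3 of these probe sets, the signal on all 3 knockout arrays lay above all 3 wild-type arrays with an unadjusted limma p under 0.01, and none of them passed the adjustment over the 643 probe sets.

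The first was the dimmer probe set of Prdx4 (1416166_a_at), a peroxiredoxin of the endoplasmic reticulum, at 5.96 ± 0.05 in wild-type and 6.39 ± 0.09 in knockout hearts (SD, n = 3), a difference of 0.43 (adjusted p = 0.202 in limma). The brighter probe set of Prdx4 differed by 0.19, also without overlap of the groups. The second was a probe set of Ncl (1415772_at), the nucleolar protein nucleolin, at 4.85 ± 0.30 and 5.50 ± 0.16, a difference of 0.65 (adjusted p = 0.298 in limma), while the other probe sets of Ncl, both brighter, differed by 0.14 and 0.27 with overlap of the groups. The third was a probe set without a gene symbol (1415852_at), at 7.31 ± 0.07 and 7.66 ± 0.06, a difference of 0.35 (adjusted p = 0.298 in limma). In the other direction, a probe set assigned to more than 1 gene, and so not named, had the smallest p of the 643 probe sets, with all knockout arrays below all wild-type arrays and a difference of -0.45 (adjusted p = 0.202 in limma). No explanation was tested for these 4 probe sets.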

How the results depend on the processing

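The covariates for the spike levels and the lists with at least 3 genes were chosen after seeing the data. Only 494 of the array's genes had values in the table used here, and they are not a random sample of its genes. With 3 arrays per genotype the fits have little power for differences near 0.3, which were called in 33.3% of simulated genes. That rate was eased by larger changes in the same simulated sets, and power is lower where few genes change. Detection calls were not used here, so dim genes such as Igf2 and Mpo have no check against background. Of the 49 named genes, 31 kept their direction in every alternative run. The count of 12 genes at an unadjusted p under 0.01 became 20 with a prior variance that follows expression, which also called 1 gene, Atp5o, at -0.28, and 22 with array weights, and ranged from 3 to 17 when each array was left out, with 7, 3, 7 and 6 without wild-type replicates 1 and 2 and knockout replicates 2 and 3. The number of lists past the threshold was 0 with an estimated correlation, 2 with the hybridisation spike covariate and 1 to 2 when each array was left out, 2 without wild-type replicate 1. The adjusted p of the ATP synthase list ran from 0.000337 to 0.0443, the latter with the hybridisation spike covariate, in all alternatives except the estimated correlation (0.0940). That of the SREBP list was 0.00943 with the hybridisation spike covariate, ran from 0.0245 to 0.340 when each array was left out, and was highest with an estimated correlation (0.428). The combined mitochondrial list and the ribosomal protein genes kept direction and a p under 0.05 in every alternative run.

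Of the named genes, 18 changed sign in at least 1 fit, among them Bpgm, Lox, Hsp90b1, Ccn1, Hspa5 and Hif1a with differences above 0.1 in size. A further quantile normalization gave 0.0353 for Lpl and 0.125 for Gja1, centring gave -0.0023 for Fabp3 and -0.0352 for Actc1, and array weights gave 0.0025 for Junb. The hybridisation spike covariate gave 0.000154 for Acadm, 0.00478 for Lpl, 0.0368 for Pdpk1, 0.170 for Gja1, 0.0605 for Junb, 0.000232 for Hif1a, -0.0488 for Bpgm and 0.0778 for Nnt. Leaving out each array in turn gave -0.0540 to 0.00666 for Lpl, -0.108 to 0.0662 for Gja1, -0.00226 to 0.0968 for Txn1, -0.135 to 0.0593 for Junb, -0.0618 to 0.00580 for Nnt, -0.0731 to 0.0387 for Igf2, -0.00303 to 0.0277 for Actc1, -0.0600 to 0.315 for Hsp90b1, -0.0142 to 0.242 for Hspa5, -0.372 to 0.153 for Lox, -0.0743 to 0.0415 for Acadm, -0.101 to 0.00587 for Pdpk1, -0.0899 to 0.00547 for Tpi1, -0.0314 to 0.247 for Ccn1 and -0.0220 to 0.128 for Mcm7. The cause was not tested.

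The labels give both genotypes replicate numbers 1 to 3 without saying that they pair hearts. Deviations of same-numbered arrays from their group means correlated at -0.15, -0.08 and 0.18, and wild-type replicate 2 correlated best with knockout replicate 1. These values give no sign that the numbers pair the arrays, but 3 arrays per genotype are too few to exclude it. With the replicate number as a block, 11 genes had an unadjusted p under 0.01, 0 passed the adjustment, and the ATP synthase list had an adjusted p = 0.00391. The alternatives for Ppargc1b and the pseudocount were not run, since that gene was not analysed here and the values are on the log2 scale.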

Other observations

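In this part, the ribosomal protein group, the union of the mitochondrial lists, the covariates, the test of the share of cardiomyocytes and the further genes named below were chosen after the values had been seen. Genes for proteins of the cytosolic ribosome, which translates most cellular mRNA, were higher in knockout hearts. Of 12 measured genes, 10 were higher and 2 lower, with 0.21 for Rps4x, 0.20 for Rpl7, 0.18 for Rpl37a and 0.17 for Rpl35, against -0.13 for Rpsa, which lay near the lower end of the scale, and 0.00 for Rplp2. The mean over the 12 genes was 10.87 ± 0.01 in wild-type and 10.99 ± 0.03 in knockout hearts (SD, n = 3), a difference of 0.12 (95% interval 0.07 to 0.17), with every knockout array above every wild-type array (exact permutation p = 0.1, the smallest that 3 against 3 allows). Camera gave p = 3.87e-04, and p = 0.0198 with an estimated correlation, which was -0.061. Adjusted over the 12 genes alone, 0 passed in limma. Of 9 further ribosomal protein probe sets assigned to several genes, 8 were higher, with a median of 0.14. The excess of the 3' over the 5' probe set of Actb, a measure of RNA quality and amplification, was lower on all knockout arrays, at 0.51 to 0.73 against 0.74 to 0.77 on wild-type arrays. That of Gapdh was 0.08 in both genotypes.

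Fkbp5, a chaperone induced by glucocorticoids, had the largest difference of the 494 genes, with a large spread among knockout hearts. It stood at 6.08 ± 0.36 in wild-type and 7.02 ± 1.04 in knockout hearts (SD, n = 3), with 6.16, 8.18 and 6.71 on the 3 knockout arrays, and the groups overlapped. Among genes without overlap of the groups, Ifrd1 differed by 0.73, Errfi1, an inhibitor of the epidermal growth factor receptor, by 0.61, Adh1, an alcohol dehydrogenase, by 0.54 and Cd83, a surface protein of activated immune cells, by 0.53. None passed the adjustment over all genes, with an adjusted p = 0.347 in limma for each of these 4. Vdac2, a pore of the outer mitochondrial membrane outside the fixed lists, differed by -0.18 without overlap of the groups. Vdac1 and Vdac3, from the same family, differed by -0.12 and -0.08 with overlap of the groups.

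The lower values of the 22 mitochondrial genes were weighed against technical and compositional explanations. Array handling that follows the hybridisation spikes may contribute. With the spike level as a covariate the difference was -0.132 (95% interval -0.217 to -0.0479), against -0.137 without it. With the Actb 3' minus 5' difference or the poly-A spike level as a covariate it was -0.137 (intervals -0.218 to -0.0554 and -0.193 to -0.0809). The hybridisation spikes and the Actb difference were lower on every knockout array, though the highest knockout and lowest wild-type arrays nearly met (9.679 and 9.688, 0.731 and 0.737). Their fits thus rest largely on differences within each genotype. Those fits cannot separate a handling or RNA quality shift shared by all knockout arrays from genotype. The poly-A spikes overlapped between the genotypes and differed by only 0.06. Their fit could therefore hardly change the difference, and adds little to that near equality. Compression of bright probe sets is argued against by random lists of other genes matched on mean expression, since the median of the mitochondrial genes lay at percentile 0 of 10000 lists. Few other genes were as bright, so these lists share many members, match less closely at the bright end, and the percentile is only a rough guide. A lower share of cardiomyocytes would lower other cardiac genes alike, and the gap between the mitochondrial genes and 4 of these (Actc1, Gja1, Fabp3 and Lpl) differed by -0.144 (interval -0.282 to -0.0065), which goes against it, but the interval reached 0.0199 without Actc1 and 0.0581 without Fabp3, so 4 genes are too few to settle it. Loss of Pgc1b is the intended biological difference of the design and a candidate explanation as well. It was not separated from composition, the mixed background, sex or genes near Ppargc1b. The fixed lists of sex-linked genes and of neighbours of Ppargc1b had no measured gene, so the values gave no check of either. Nor was loss of Pgc1b separated from any batch of arrays that followed the genotypes. Hybridisation batches are not given in the sources used here, and the spikes were lower on all knockout arrays.

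For the ribosomal protein genes, the difference with the hybridisation spike level as a covariate was 0.132 (interval 0.0367 to 0.227), against 0.120 without it. With the Actb 3' minus 5' difference as a covariate it was 0.124 (interval 0.0296 to 0.218), and with the poly-A spike level, a control of labelling, 0.121 (interval 0.0560 to 0.186). The median lay at percentile 100 of 10000 matched lists of other genes, which also share many members because few other genes were as bright. The group was chosen after its values had been seen, so this percentile is not independent support. The matched lists themselves had a median of 0.0049, so other bright genes did not rise as a group. The poly-A spikes differed by only 0.06 between the genotypes, so their fit could hardly change the difference and adds little to that near equality. The hybridisation spikes and the Actb difference did not overlap between the genotypes. Their fits therefore cannot separate a handling or RNA quality shift shared by all knockout arrays from genotype. The effect of genotype stays open, as do the mixed background, sex and genes near Ppargc1b. Handling, labelling, RNA quality, differences in amplification, or a batch of arrays that followed the genotypes stay open too.

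The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. As many genes at an unadjusted p under 0.01 as with the genotypes were seen in 2 of the 10 splits, the genotype split included, with 12 genes for the genotypes and 13 as the highest of the others, which set wild-type replicate 1 with knockout replicates 2 and 3 against the rest. As many lists past the threshold were seen in 2 of the 10 splits, with 1 list for the genotypes and 1 as the highest of the others.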
